A study of Homo sapiens with 6 samples.

How the data were processed

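Total RNA of 6 samples, 3 of the parental H460 line and 3 of a cisplatin-resistant line derived from it, had been extracted with Trizol and a column clean-up, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds 1 log2 value per probe set and array, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA summarises the probes of a probe set on the log2 scale after background correction and quantile normalization, so that overall differences in signal between arrays are removed and small differences of dim probe sets are compressed. The versions, the background options, the probe annotation and the genome build behind these values are not given in the sources used here. The table has 33297 rows and 6 columns with 0 missing values, and holds no detection calls, so that signal over background is unknown. Each column was assigned to its sample through the labels. No scan date or batch was used here, and no batch effect was tested.

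Rows were named from the platform annotation paired with the table. Of the 33297 rows, 19460 had 1 gene symbol, 1754 had several and 12083 had none. Symbols were updated through the gene identifier to the RefSeq annotation of GRCh38.p14 (19429 of 19460 matched), which was otherwise used only for gene lengths and for the order of genes along chromosomes. No coordinates are given, since the build of the array annotation is not stated. Rows with several symbols or none were left out of the gene tests. For 769 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was kept, which left 18417 genes. In 0 of the 769 genes were probe sets called in opposite directions over all rows of the table, and in 20 only some of the probe sets were called.

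The resistant and parental groups were compared with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, on all 6 arrays, with no block and no filter on level. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 18417 genes. Counts of at least 2-fold change add an absolute log2 difference of at least 1. Intervals are 95% intervals from the moderated fit. The same procedure was tested on simulated data on 18417 genes for this comparison, with 200 genes changed by known amounts. It called 0% of the genes changed by 0.25 on the log2 scale, 54% at 0.5, 98% at 1 and 100% at 2. Of 131 calls, 5 were unchanged genes, and 0 genes and 0 lists were called when no change was simulated. Genes were simulated independently of one another. The count of 0 lists therefore does not show how often lists of correlated genes pass by chance. The number of arrays limits the precision. A difference of 0.25 was below what this procedure detected in the simulated data, where fewer genes changed than were called in the real data. The adjustment is less strict with more calls, and in the real data WSB1 was called at -0.26 (limma adjusted p = 0.0458).

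Before the data were examined, 37 gene lists of DNA repair, drug transport, stress, metabolism, signalling, identity and other cell types were written from general knowledge. Of their 1125 genes, 992 were measured. Lists with at least 5 measured genes were tested with limma's camera with a preset correlation of 0.01, adjusted over the 37 lists, and beside it with camera with an estimated correlation and with fry. The lists overlap in part, and several hold genes that lung carcinoma cells express themselves. A panel of 20 genes was fixed at the same time, of which 17 were measured.

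Genes were named by a rule also fixed before the data were examined. It takes the 12 genes with the largest positive and the 12 with the largest negative log2 difference among called genes whose groups do not overlap. It adds up to 4 called members of each list with the largest difference, or up to 2 with the smallest p where none was called, the genes of the panel, and the genes at the ends of runs of neighbouring genes.

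Genes were ordered along chromosomes, and the largest absolute mean log2 difference over 25 neighbouring genes was compared with that in 1000 shuffles of the gene order. Alternatives were a further quantile normalization, centring of each array, a trend or a robust prior in eBayes, array weights, a filter on level, the mean of all probe sets, every row tested on its own, the replicate number as a block, limma's treat test, windows of 50 genes, and leaving out each array in turn. Further window statistics were added after the data were examined. The number of splits of 6 arrays into 3 and 3 is 10.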

Results

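Gene expression was measured on Affymetrix arrays in H460 cells, an established human large cell lung carcinoma line, and in a cisplatin-resistant line derived from them. Cisplatin is a platinum drug that crosslinks bases in DNA. Each group had 3 arrays, labelled as biological replicates with no further account of the cultures, so that p-values measure only the spread between these samples, which may be technical. The labels used here give no drug dose, no length of selection, and no statement of whether the drug was present at harvest. The values are log2 expression after RMA, on which a difference of 1 is a 2-fold change, and differences are given as resistant minus parental. The median over the 18417 genes tested lay between 6.45 and 6.47 on each of the 6 arrays. The number of arrays limits the precision.

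The design compared the 3 resistant with the 3 parental arrays, and asked which transcripts differ between the drug-resistant line and the line it came from. The first principal component held 58.2% of the variance and separated the groups. The second component held 14.5%, and its sign set parental replicate 1 and resistant replicates 1 and 2 against the other arrays of both lines. Pearson's r across genes, which are not independent replicates, ranged from 0.995 to 0.997 between arrays of 1 group and from 0.989 to 0.991 between arrays of different groups. In limma, 1347 of 18417 genes (7.31%) differed at a Benjamini-Hochberg adjusted p under 0.05, of which 679 were higher and 668 were lower in resistant cells. The change reached 2-fold for 66 higher and 101 lower genes, and 4-fold for 7 higher and 27 lower genes. The median absolute log2 difference of the 1347 genes was 0.46, against a median SD within a group of 0.095 (parental) and 0.090 (resistant). Values of the groups did not overlap for 4639 genes (25.2%), where chance gives 10% with 3 against 3. The count of 1347 genes past the threshold was 865 without resistant replicate 1 and 877 without resistant replicate 2. The count of 167 genes changed at least 2-fold was 99 when only genes above the median level were tested, and limma's treat test of a change beyond 2-fold passed 70 genes.

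**Figure D1:**
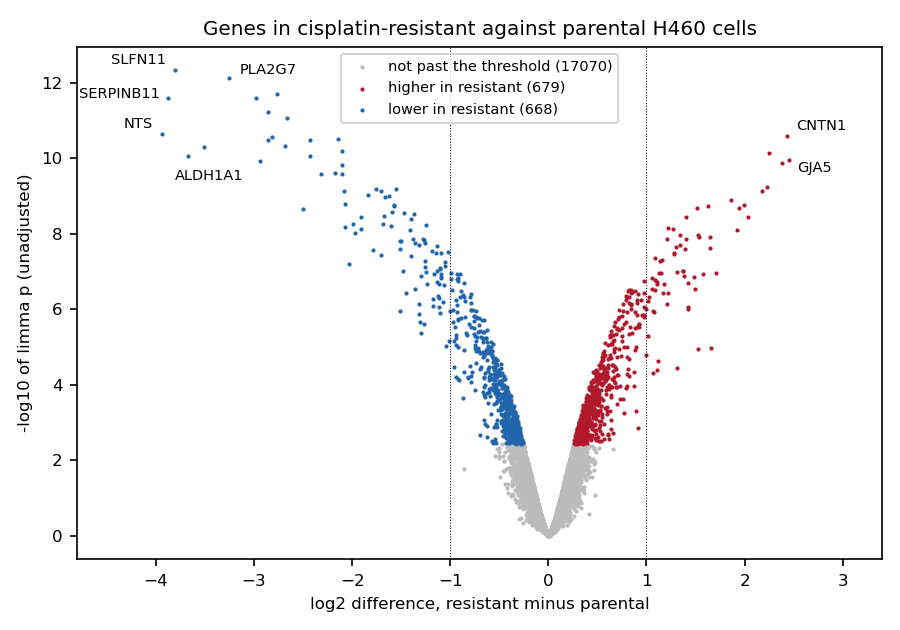
Log2 difference (resistant minus parental) against the -log10 unadjusted limma p of each of the 18417 genes. Coloured points are the 679 higher and 668 lower genes at an adjusted p under 0.05, dotted lines mark 2-fold, and the points farthest from 0 lie on the lowered side.

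The genes with the largest measured decrease were NTS, SERPINB11 and SLFN11. NTS, which encodes the secreted peptide neurotensin, fell from 8.45 ± 0.27 to 4.51 ± 0.094 (mean log2 value ± SD, n = 3), a 15.4-fold change. SERPINB11, of the serpin family of protease inhibitors, fell from 9.68 ± 0.073 to 5.81 ± 0.18, or 14.6-fold. SLFN11, a protein that blocks stressed replication forks, fell from 7.63 ± 0.071 to 3.82 ± 0.11, a log2 difference of -3.81 (limma adjusted p = 6.70e-09). FAM216B (log2 difference -3.67) and RAB3C (-3.51), a small GTPase of regulated secretion, followed. Secreted and metabolic enzymes were PLA2G7 (-3.25), a phospholipase that degrades platelet-activating factor, ACSS3 (-2.97), a mitochondrial acyl-CoA synthetase, and ALDH1A1 (-2.94), a retinaldehyde dehydrogenase. TMPRSS15 (-2.86), the protease enteropeptidase, CLTRN (-2.86), the membrane protein collectrin, MCAM (-2.81), a cell adhesion molecule, and SCN3A (-2.77), a voltage-gated sodium channel, completed the 12. The SE of these 12 differences lay between 0.068 (SCN3A) and 0.13 (FAM216B). Of the 27 genes lowered at least 4-fold, 21 had a resistant mean below the median level of all genes, and 12 lay in the lowest 25% of levels. The resistant means of NTS, SLFN11 and FAM216B lay at the percentiles 19.0, 9.05 and 7.11 of all genes. Since signal over background is unknown, a difference that ends at so low a level is a lower bound where that level is background, and the order of the 12 is that of the measured values.

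Among the raised genes, GJA5, a gap junction connexin, rose from 8.02 ± 0.14 to 10.47 ± 0.098, or 5.47-fold. CNTN1, a neuronal adhesion molecule of the immunoglobulin superfamily, rose from 6.13 ± 0.11 to 8.56 ± 0.030, or 5.41-fold (adjusted p = 4.47e-08). COL3A1, the chain of type III collagen, rose from 7.32 ± 0.10 to 9.70 ± 0.13, or 5.20-fold. ATP11A (2.25), a phospholipid flippase, ANTXR2 (2.23), a receptor of anthrax toxin, and ADARB1 (2.18), an adenosine deaminase that edits RNA, followed. ROBO1 (2.03), a receptor of Slit proteins, PHLDB2 (2.00), TPM2 (1.94), a tropomyosin, PHACTR2 (1.93), FAM83A (1.86) and CP (1.71), the copper-carrying ferroxidase ceruloplasmin, made up the 12. The SE of the 12 lay between 0.078 (CNTN1) and 0.13 (CP). The parental mean of CP lay at the percentile 7.16 of all genes, so that its difference is likewise a lower bound where that level is background. All 24 genes named here as most lowered or most raised kept their call in every alternative fit that tested them.

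**Figure D2:**
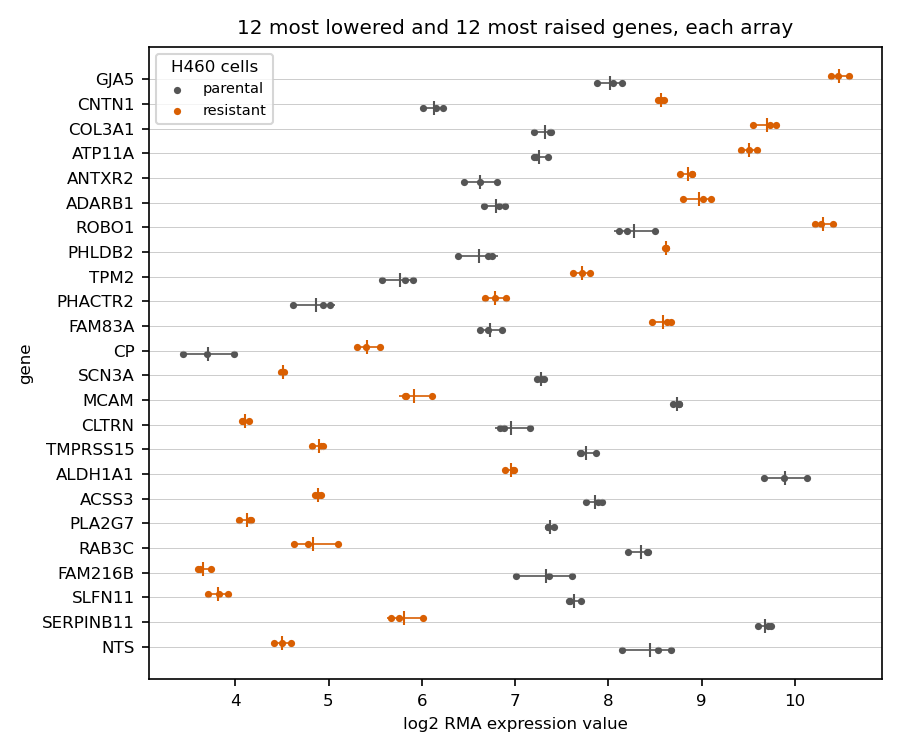
Log2 RMA expression value on each array (points), with the mean (tick) and SD (line) of the 3 parental and the 3 resistant arrays, for the 12 most raised (top) and 12 most lowered genes. In each gene the 3 arrays of one group lie on one side of the 3 of the other, with NTS means of 8.45 and 4.51 and GJA5 means of 8.02 and 10.47.

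Gene lists written before the data were examined were counted by gene and tested with limma's camera, which compares the members of a list with all other genes. Of 37 lists, 4 passed at an adjusted p under 0.05: genes of cholesterol and fatty acid synthesis and the metallothioneins shifted lower, and replication-dependent histone genes and the Fanconi anaemia and homologous recombination genes shifted higher. These calls use a preset correlation between genes of 0.01. With a correlation estimated for each list, 0 of 37 passed in camera, the lowest adjusted p was 0.873, and 1 list had an unadjusted p under 0.05. Other splits of the 6 arrays into 3 and 3 passed up to 9 lists with the preset correlation. These splits mix the groups unevenly and keep part of any difference between them. Of the lists in the split with 9, however, only the Fanconi list passed in the real split. A remaining difference between the groups does not readily account for the rest, which weakens the 4 list calls. By fry, which does not compare a list with other genes, the members of 9 lists moved on balance one way at an adjusted p under 0.05. Its test for change in either direction passed 36 lists. A few changed members can give this where 7.31% of all genes were called, so that this count says little about the lists. The 9 were extracellular matrix genes, epithelial markers and NF-kB genes, on balance higher, and NRF2 targets, stem cell genes, metallothioneins, cholesterol and fatty acid synthesis, receptor tyrosine kinases and ATF4 genes, on balance lower. The Fanconi list (adjusted p = 0.149) and the histone genes (adjusted p = 0.0632) were not among them. The sign of the median, the mean and the camera test was not the same in 11 lists: platinum and copper transport, ABC transporters, NRF2 targets, glutathione S-transferases, interferon-stimulated genes, TGF-beta targets, the Wnt, Notch and Hedgehog genes, extracellular matrix genes, and neuroendocrine, lung and fibroblast markers.

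**Figure D3:**
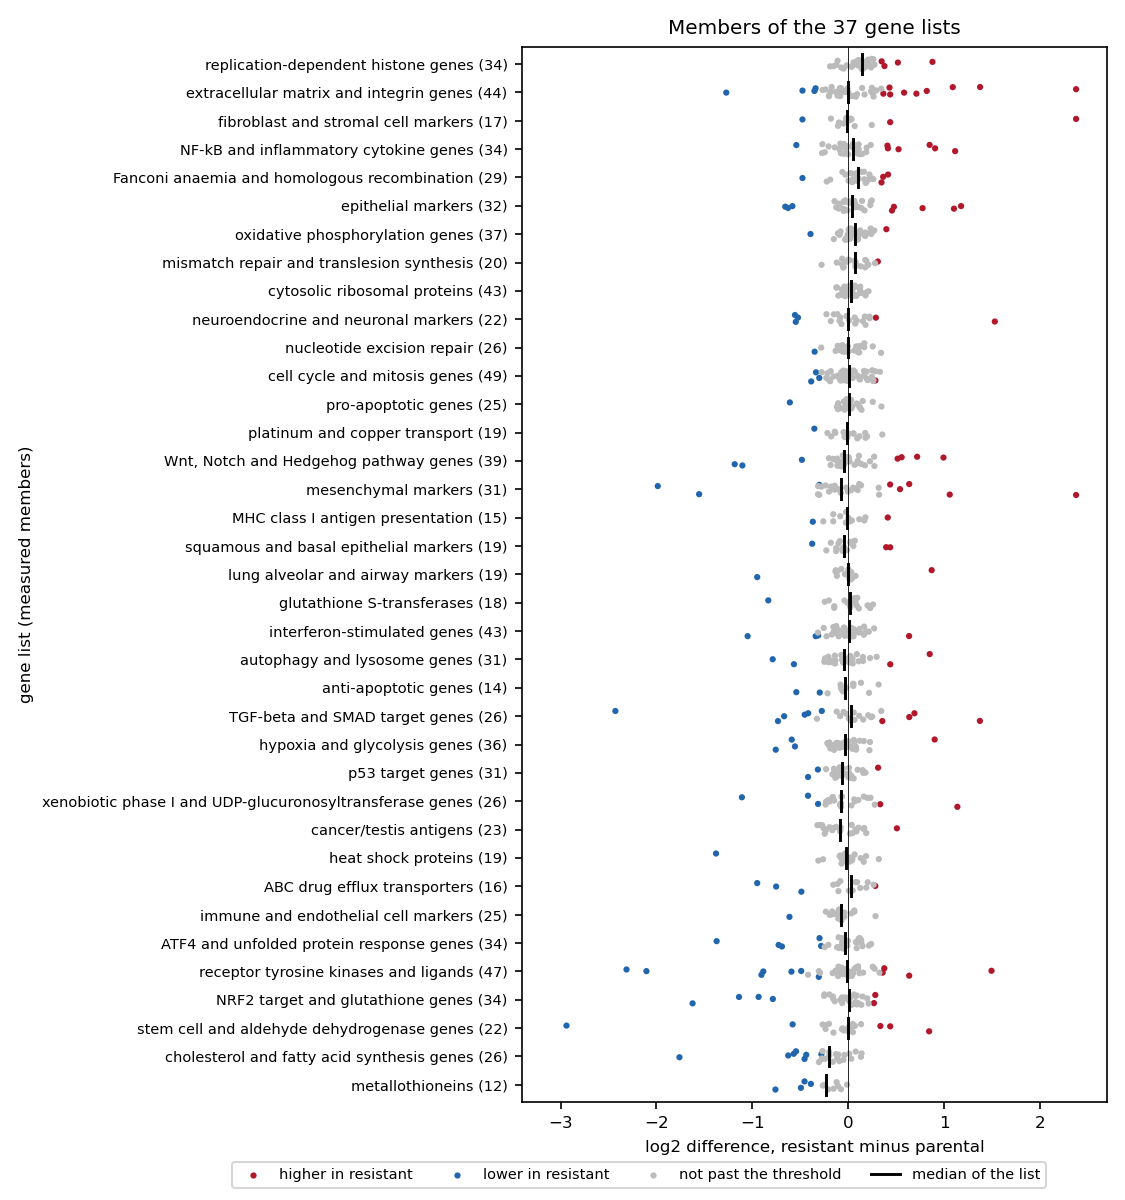
Log2 difference (resistant minus parental) of each measured member of the 37 gene lists, 1 row per list in the order of the list means, with the number of measured members in parentheses. Red and blue points passed the threshold over all genes as higher or lower, grey points did not, and the black tick is the list's median, which lies lowest for the metallothioneins (-0.23) and highest for the replication-dependent histone genes (0.15).

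Metallothioneins, small proteins that bind metals, were lower in resistant cells. Of 12 measured, 0 rose and 4 fell (0 and 7 adjusted over the list alone), and all 12 differences were negative (camera adjusted p = 2.08e-04, and adjusted p = 0.873 with an estimated correlation). MT2A fell by 0.76 ± 0.085 (log2 ± SE), MT1G by 0.49, MT1F by 0.46 and MT1X by 0.39. Among the NRF2 target and glutathione genes, 2 of 34 rose and 4 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.611). The 4 that fell were the aldo-keto reductases AKR1C3 (-1.62), AKR1C2 (-1.14) and AKR1C1 (-0.79), and the carbonyl reductase CBR1 (-0.93). Metallothioneins and AKR1C genes are families of near-identical sequence, whose probe sets may read one another, and another probe set of AKR1C1 differed by 0.03. Of the glutathione S-transferases, 0 of 18 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.959), namely GSTO2 (-0.83). GSTP1 differed by 0.09 (95% interval -0.07 to 0.25). Calls lost when 1 array was left out were those of MT1F (parental 2 or 3, resistant 1 or 3; adjusted p up to 0.107) and MT1X (any array but resistant 2; up to 0.132).

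Among platinum and copper transporters, 0 of 19 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.967). The gene that fell was LRRC8D (-0.35 ± 0.077), a subunit of volume-regulated anion channels. The copper importer SLC31A1 differed by -0.14 (95% interval -0.29 to 0.01) and the copper exporters ATP7A and ATP7B by 0.05 (-0.10 to 0.21) and 0.36 (0.13 to 0.59; adjusted p = 0.0715). ATP7B passed without parental replicate 3 (adjusted p = 0.0125). LRRC8A differed by 0.18 (-0.03 to 0.39). Of the ABC drug efflux transporters, 1 of 16 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.728). ABCA3 (-0.95), ABCG2 (-0.75) and ABCB1 (-0.49), the last 2 exporters of many drugs, fell, ABCC3 (0.28) rose, and ABCC2 differed by 0.08 (-0.09 to 0.24). The resistant mean of ABCB1 lay at the percentile 19.3 of all genes. The call of LRRC8D was lost without parental 2 or any resistant array (adjusted p up to 0.0814), and that of ABCC3 without any 1 of the 6 arrays (0.0645 to 0.114).

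Genes of the Fanconi anaemia pathway and homologous recombination, which repair DNA crosslinks, were shifted higher. Of 29 measured, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0151, and adjusted p = 0.932 with an estimated correlation). The arrays of the groups overlapped in the mean of the list's members. Relative to the mean of all 6 arrays, it was -0.0056 on resistant 3 and 0.0075 on parental 1. It was 0.084 on resistant 1 and 0.067 on resistant 2, against -0.091 on parental 2 and -0.063 on parental 3. The sign of this mean thus divided the arrays as the second principal component did, across both lines. The helicase BRIP1 (0.42), the ubiquitin ligase FANCL (0.37) and the nuclease FAN1 (0.35) rose, and PALB2 (-0.48), a mediator of recombination, fell. BRCA1 differed by 0.19 (95% interval 0.03 to 0.35; adjusted p = 0.159) and lies in a stretch of chromosome 17 where the 163 genes above the median level had a median of 0.17 and the 154 dimmer genes one of -0.01. PALB2 lies in a stretch of chromosome 16 where the 50 genes above the median level had a median of -0.32 and the 51 dimmer genes one of -0.04. Of the nucleotide excision repair genes, 0 of 26 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.728). This was ERCC1 (-0.35 ± 0.090; adjusted p = 0.0446), while its partner nuclease ERCC4 differed by -0.11 (-0.36 to 0.14) and XPA by -0.06 (-0.24 to 0.12). In mismatch repair and translesion synthesis, 1 of 20 rose and 0 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.285), the gene being REV3L (0.31), the catalytic subunit of polymerase zeta. The Fanconi list was past the threshold neither among genes above the median level (0.0858) nor without parental 2 (0.0890), parental 3 (0.0596) or resistant 1 (0.0960). Single calls lost with 1 array left out were those of BRIP1 (resistant 1; 0.0507), FANCL (resistant 1; 0.05), FAN1 (parental 1 or 2, resistant 1 or 2; up to 0.101), REV3L (parental 2 or 3, resistant 1 or 2; up to 0.102) and ERCC1 (any array but parental 2; up to 0.151).

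Replication-dependent histone genes, which supply histones in S phase, were higher. Of 34 measured, 4 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 2.08e-04, and adjusted p = 0.873 with an estimated correlation). Relative to the mean of all 6 arrays, the mean of the list's members was -0.014 on resistant 1, close to -0.049 on parental 3. It was 0.12 on both resistant 2 and resistant 3, so that the shift rests mainly on these arrays. H2BC14 rose by 0.88 ± 0.074, H4C4 by 0.52, H2BC9 by 0.38 and H2AC4 by 0.35. These genes are near-identical in sequence, so that the signal of each may include others. Of the cell cycle and mitosis genes, 1 of 49 rose and 3 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.728). The mitotic kinase AURKA (-0.39), the phosphatase CDKN3 (-0.34) and the kinesin KIF20A (-0.30) fell, and the kinase AURKB (0.28) rose. With 1 array left out, calls were lost for H2AC4 (parental 2, resistant 2 or 3; adjusted p up to 0.0749), CDKN3 (any array but parental 3; up to 0.106), KIF20A (any array; up to 0.0939) and AURKB (any array; up to 0.136).

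Of the p53 target genes, 1 of 31 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.634). MDM2, the ubiquitin ligase of p53, rose by 0.31 ± 0.068, while the polo-like kinase PLK2 (-0.42) and CYFIP2 (-0.32) fell. MDM2 lies in a stretch of chromosome 12 where the 45 genes above the median level had a median of 0.33 and the 36 dimmer genes one of 0.04. CDKN1A, the cell cycle inhibitor p21, differed by -0.01 (95% interval -0.18 to 0.16). Among anti-apoptotic genes 0 of 14 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.728), the 2 being TNFAIP3 (-0.54) and MCL1 (-0.30). BCL2 differed by 0.05 (-0.12 to 0.23) and BCL2L1 by 0.32 (0.11 to 0.52; adjusted p = 0.0715). BCL2L1 passed with resistant 3 left out (0.0133), with array weights, with an intensity trend, and among genes above the median level. Among pro-apoptotic genes 0 of 25 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.728), namely the initiator caspase CASP9 (-0.61). Calls were lost for MDM2 (any array but resistant 3; adjusted p up to 0.0814), CYFIP2 (any but parental 3; up to 0.137) and MCL1 (any but resistant 1; up to 0.135).

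Genes of the extracellular matrix and integrins changed in both directions. Of 44 measured, 9 rose and 4 fell (14 and 6 adjusted over the list alone, camera adjusted p = 0.174), and by fry they moved on balance higher (adjusted p = 0.0157), with a median of -0.0047 and a mean of 0.13. COL3A1 (2.38), the collagen COL12A1 (1.38) and the integrin ITGB8 (1.09) rose, and the collagenase MMP1 (-1.27) fell. Of the mesenchymal markers 5 of 31 rose and 3 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.809). N-cadherin, CDH2, rose (1.06), whereas the transcription factor ZEB2 (-1.99) and the cadherin CDH11 (-1.55) fell. The other probe set of ZEB2 differed by -0.66 and was not past the threshold over all rows of the table (adjusted p = 0.141). Of the epithelial markers 5 of 32 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.258), with the desmosome genes PKP2 (1.18) and DSP (1.10) and the claudin CLDN7 (0.78) higher and CLDN4 (-0.66) lower. Among fibroblast and stromal markers 2 of 17 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.728). They were COL3A1, COL1A1 (0.44) and lumican, LUM (-0.48).

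Signalling genes moved both ways. Of the TGF-beta and SMAD targets, 4 of 26 rose and 6 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.836). The activin antagonist FST (-2.43 ± 0.079) and the receptor TGFBR1 (-0.73) fell, and TGFBR3 (1.37) and ID2 (0.69) rose. Of the receptor tyrosine kinases and their ligands and regulators, 4 of 47 rose and 7 fell (7 and 10 adjusted over the list alone, camera adjusted p = 0.604). The ephrin receptor EPHA4 (-2.31), the IGF-binding protein IGFBP3 (-2.10) and the ERK phosphatase DUSP6 (-0.90) fell, and IGFBP4 rose 2.82-fold. In the Wnt, Notch and Hedgehog list 4 of 39 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.959), with the Wnt antagonist DKK1 (-1.18) and NOTCH3 (-1.10) lower and HES1 (0.99) and WNT5A (0.72) higher. Of the stem cell and aldehyde dehydrogenase genes 3 of 22 rose and 2 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.634). ALDH1A1 (-2.94) and KLF4 (-0.58) fell, and ALDH2 (0.84) and SOX2 (0.44) rose. This list passed as lower among genes above the median level (0.00661), and the call of SOX2 was lost without resistant 2 or 3 (adjusted p up to 0.0516).

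Genes of cholesterol and fatty acid synthesis were lower in resistant cells. Of 26 measured, 0 rose and 7 fell (0 and 13 adjusted over the list alone, camera adjusted p = 6.83e-06, and adjusted p = 0.873 with an estimated correlation), and 21 differences were negative. The fatty acid desaturases FADS2 (-1.76 ± 0.078) and FADS1 (-0.57), the sterol oxidase MSMO1 (-0.63) and squalene epoxidase, SQLE (-0.54), fell. Of the ATF4 and unfolded protein response genes 0 of 34 rose and 5 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.380). They included the tryptophanyl-tRNA synthetase WARS1 (-1.37), cystathionase, CTH (-0.73), the lipoprotein receptor VLDLR (-0.69) and the chaperone HSPA5 (-0.30). Among heat shock proteins 0 of 19 rose and 1 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.728), the small chaperone CRYAB (-1.38). The call of HSPA5 was lost without any 1 of the 6 arrays (adjusted p 0.0628 to 0.113).

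In the hypoxia and glycolysis list 1 of 36 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.634). The glucose transporter SLC2A1 (0.90) rose, and carbonic anhydrase CA12 (-0.76), the aldolase ALDOC (-0.59) and the enolase ENO2 (-0.56) fell. Of the oxidative phosphorylation genes 1 of 37 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.154). NDUFA2 (0.40), of complex I, rose, and UQCRC2 (-0.39), of complex III, which lies in the chromosome 16 stretch that holds PALB2, fell. The list passed as higher without parental 1 (0.0332) or resistant 1 (0.0383). Of the autophagy and lysosome genes 2 of 31 rose and 2 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.728), namely HEXA (0.85) and the protease CTSS (0.44), and CTSL (-0.79) and WIPI1 (-0.57). Of the cytosolic ribosomal proteins 0 of 43 passed in limma, with 3 at an unadjusted p under 0.05 (0 and 0 adjusted over the list alone, camera adjusted p = 0.393). RPL27 differed by 0.21 and RPS7 by 0.19, both past the threshold with an intensity trend. The other probe set of RPS7 differed by 0.04. In xenobiotic metabolism 2 of 26 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.634), among them TIPARP (1.14) and the cytochromes CYP3A4 (0.33), CYP24A1 (-1.11) and CYP1B1 (-0.42). The rise of CYP3A4 lay between means at the percentiles 1.35 (parental) and 4.70 (resistant) of all genes, at the bottom of the range of the arrays. Calls were lost for NDUFA2 (any array but resistant 1; adjusted p up to 0.116), CTSS (any but parental 3; up to 0.14) and CYP3A4 (parental 3, resistant 1 or 2; up to 0.0694).

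Of the NF-kB and inflammatory cytokine genes, 6 of 34 rose and 1 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.172). The interleukins IL1B (1.12 ± 0.15) and IL1A (0.91) and the chemokine CCL20 (0.85) rose, and TNFAIP3 (-0.54), an inhibitor of NF-kB signalling, fell. Of the interferon-stimulated genes 1 of 43 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.728). IFITM2 (-1.05), the ubiquitin-conjugating enzyme UBE2L6 (-0.34) and OAS1 (-0.31) fell, and the RNA sensor RIGI (0.64) rose. This list passed as lower among genes above the median level (0.0415). In MHC class I antigen presentation 1 of 15 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.993), the peptidase ERAP2 (0.41) and the proteasome subunit PSMB9 (-0.37). Calls were lost for RIGI (parental 2 or 3, resistant 2 or 3; adjusted p up to 0.107), UBE2L6 (any array but parental 2; up to 0.0950), OAS1 (any array; up to 0.0710), ERAP2 (parental 3 or resistant 3; up to 0.0524) and PSMB9 (parental 1 or 3, resistant 1 or 3; up to 0.103).

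Markers of other cell types were counted in the same way. Of the neuroendocrine and neuronal markers 2 of 22 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.959), with the synaptic protein SNAP25 (1.53) higher and ENO2 (-0.56), NCAM1 (-0.55) and GAP43 (-0.52) lower. Of the squamous and basal markers 2 of 19 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.767), namely SOX2 (0.44), the desmosomal cadherin DSC3 (0.40) and the keratin KRT15 (-0.38). Of the lung alveolar and airway markers 1 of 19 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.767), the secretoglobin SCGB3A2 (0.87) and the lipid transporter ABCA3 (-0.95). Of the immune and endothelial markers 0 of 25 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.172), the lysosomal protein CD68 (-0.61). Among cancer/testis antigens 1 of 23 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.634), namely PRAME (0.51). Calls were lost for NCAM1 (parental 2 or 3, resistant 1 or 3; adjusted p up to 0.145), SOX2 (resistant 2 or 3; 0.0516), DSC3 (parental 2 or 3, resistant 1; 0.0691), KRT15 (any array but parental 1; 0.107) and PRAME (resistant 1 or 2; 0.0594). The parental mean of SCGB3A2 and both means of KRT15 lay in the lowest 25% of levels. The means of DSC3 lay at the percentiles 6.66 (parental) and 12.5 (resistant) of all genes. NCAM1 also lost its call after a further quantile normalization.

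A panel of 20 genes linked in general knowledge to the cisplatin response was fixed before the data were examined, and 3 of the 20 were not analysed here. Of the 17 measured, 5 were past the threshold. SOX2 and MDM2 rose, and ALDH1A1, MT2A and ERCC1 fell, with the values given above. The other 12 (ATP7A, ATP7B, SLC31A1, LRRC8A, ABCC2, GSTP1, XPA, ERCC4, BRCA1, BCL2, BCL2L1 and CDKN1A) were not past it, and their intervals, also given above, show the sizes these arrays leave open.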

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

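The count of splits in which each single list passed, and the comparison of the lists of single splits, were chosen after the result was seen. The other tests of this part were not.

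Rows of the table that the gene comparison left out carried differences too. Tested over all rows with limma, 9 rows with no gene symbol and 3 rows with several symbols were at least 2-fold higher in resistant than in parental cells, at an adjusted p under 0.05. In the other direction, 6 rows with no symbol and 2 rows with several symbols were at least 2-fold lower. Of the 13837 rows outside the gene comparison, 194 were past the threshold. They are unnamed here, and no explanation of them was tested.

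The arrays were regrouped into every other split of 3 against 3. The real split gave 1347 genes past the threshold, the highest other split gave 0, and 1 of the 10 splits, the real one itself, gave as many. At an unadjusted p under 0.05, limma passed 3624 genes in the real split and 374 to 1239 in the others. For genes changed at least 2-fold, the real split gave 167 and the highest other 0, and 1 of the 10 splits, the real one itself, gave as many. With 10 splits no share under 0.05 can be reached. Each other split puts arrays of both lines on the same side, which widens the spread there. Few calls are therefore expected in the other splits whenever the lines differ, and their counts are no measure of chance.

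For the gene lists the real split passed 4 lists and the highest other split 9. As many as in the real split, or more, passed in 3 of the 10 splits, the real one included. The split with 9 lists sets parental 1, resistant 1 and resistant 2 against the rest, as does the sign of the second principal component. This split called 0 genes (1239 at an unadjusted p under 0.05 in limma). Genes of cholesterol and fatty acid synthesis passed in 4 other splits, replication-dependent histone genes in 3, and the metallothioneins and the Fanconi list in 1 each. Each other split mixes the groups unevenly, so that part of any difference between them stays between its sides. A list with a real shift can therefore pass there, and these counts do not show what chance alone would give. Of the lists in the split with 9, however, only the Fanconi list passed in the real split. Nucleotide excision repair and cell cycle genes were at a camera adjusted p of 0.728 each in the real split. A remaining difference between the groups does not readily account for such lists. At the preset correlation lists can thus pass on other differences between arrays, which weakens the 4 list calls. The splits are too few for a share under 0.05.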

How the results depend on the processing

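Alternatives were fixed before the data were examined, except 5 of the window statistics, which were chosen after. The count of changed genes ran from 1046 (replicate block) to 1993 (intensity trend) over the fits on all genes, and was 1629 among genes above the median level. With 1 array left out it ran from 865 (without resistant 1; 877 without resistant 2) to 1118, where fewer samples are tested. Genes changed at least 2-fold were 99 among genes above the median level, where fewer genes are tested, 70 with treat, a stricter test by construction, and 166 to 176 in the other fits by gene, while 192 rows passed when every row was tested. The share of changed genes higher in resistant cells stayed within 10 percentage points of 50.4%. The values gave no clear sign that replicate numbers pair the samples, which so few pairs cannot rule out. Deviations of same-numbered arrays correlated at -0.01, -0.11 and 0.13, and not every array correlated best with its own number. The replicate block gave 1046 genes, 1010 of them shared with the fit without it, 167 genes at 2-fold, and 4 lists.

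With an estimated correlation 0 lists passed (Fanconi 0.932, metallothioneins, histones and cholesterol and fatty acid synthesis 0.873 each). Among genes above the median level the Fanconi list was at 0.0858, stem cell genes at 0.00661 and interferon-stimulated genes at 0.0415. With 1 array left out, the Fanconi list ranged from 0.00294 to 0.0960, and passed neither without parental 2 (0.0890), parental 3 (0.0596) nor resistant 1, and the oxidative phosphorylation list ranged from 0.0332 to 0.515, and passed without parental 1 or resistant 1 (0.0383). Robust eBayes does not enter camera. Windows gave largest sizes of 0.267 (50 genes), 0.414 (25 genes above the median level), 0.348 (50 genes above it), and as running medians 0.349 (25 genes), 0.307 (51 genes), 0.393 (25 above it) and 0.328 (51 above it), against 0.31 for 25 genes. The cause of the list and window changes was not tested. No called result reversed. Of 153 named genes, ends of stretches included, 130 were past the threshold and 98 of these in every alternative that tested them. Of the other 23, 15 were past it in none. Signal over background is unknown for these arrays.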

Other observations

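The means over 25 and 50 neighbouring genes, and over 25 above the median level, were planned with their shuffles; the running medians, the mean over 50 genes above the median level, the splits, the tests of gene length and of held-out genes, the limit of 25 genes within which stretches were joined, and the tests of lists inside and outside the stretches were chosen after results were seen.

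Neighbouring genes above the median level moved together in parts of the genome. In the gene order of GRCh38.p14, genes above the median level formed 7 stretches in which the running median over 51 genes passed the 95th percentile of 1000 shuffled orders. A joining limit of 10 genes, tried first, gave 9 stretches and a share of held-out genes on the side of their stretch of 0.856, against 0.848 with the limit used. The clearest were on chromosome 12, from LLPH to ATP2B1, where 45 such genes had a median log2 difference of 0.33, with 29 called higher and 4 lower, and on chromosome 16, from CEP20 to KIF22, where 50 had a median of -0.32, with 28 called lower and 0 higher (94% negative). The other raised stretches lay on chromosome 15 from GJD2 to CRTC3 (247 genes, median 0.16), chromosome 17 from WSB1 to GRN (163, 0.17), chromosome 19 from RNASEH2A to ADGRL1 (25, 0.29) and chromosome 6 from H4C4 to ABT1, which holds histone genes of near-identical sequence (14, 0.14), and the other lowered one on chromosome 14 from SRP54 to SETD3 (182, -0.13). Over whole chromosomes, 84.5% of the 297 genes above the median level on chromosome 15 were higher in resistant cells, and 83.0% of the 289 on chromosome 14 were lower. The dimmer genes of the same stretches had medians closer to 0: 0.04 over 36 genes on chromosome 12, -0.04 over 51 on chromosome 16, -0.03 over 195 on chromosome 15, -0.01 over 154 on chromosome 17, -0.03 over 16 on chromosome 19, -0.01 over 8 on chromosome 6 and -0.06 over 165 on chromosome 14. The stretches held 7.90% of the 9195 genes above the median level, and, since they were found from the differences of these genes, their medians and calls describe them and test nothing. Several of the most lowered genes lie inside raised stretches: NTS (-3.94) and ACSS3 (-2.97) on chromosome 12 and SLFN11 (-3.81) on chromosome 17. So do DUSP6 (chromosome 12), CA12 (15), and ALDOC and KRT15 (17), which fell. Named genes in a stretch of their own direction were H4C4 and H2BC9 (6), MDM2 (12), CDKN3 (14), HEXA (15), PALB2 and UQCRC2 (16), and IGFBP4, BRCA1 and RPL27 (17).

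Of the 3 planned statistics the main one did not pass: the largest mean over 25 genes, 0.31 in size at XYLT1 on chromosome 16 and negative, was reached in 111 of 1000 shuffles. The other 2 passed, with 1 of 1000 shuffles as large for means over 50 genes and 0 of 1000 for means over 25 genes above the median level. Of all 8 window statistics tried, 7 passed, with under 50 of 1000 shuffles as large, and for the running median over 51 genes above the median level, which peaked on chromosome 12 with a positive sign, the count was 0 of 1000 (0.328, against a 95th percentile of 0.117). In 1 of the 10 splits of the arrays, the real one itself, the largest running median was as large (real 0.328, highest other 0.162). Splits this few give no share under 0.05, and the other splits mix both lines and keep only part of any difference between them.

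A gain or loss of chromosome segments in the resistant line is a candidate explanation, offered as a hypothesis. Against chance order stand 0 of 1000 shuffles for the running median over 51 genes above the median level, chosen after results were seen. Of the planned statistics, means over 50 genes (1 of 1000) and over 25 genes above the median level (0 of 1000) also passed. The main planned one, the mean over 25 genes, did not pass (111 of 1000). Against gene length and level as the whole source stands that each stretch kept at least 0.799 of its median after a loess on both. In stretches found from every second gene, a share of 0.848 of the 342 genes held out lay on the side of the stretch, which a copy number change would give, but so would a shared regulation of neighbouring genes. These genes do not cover all stretches alike: none was found again on chromosome 6, where 0 genes were held out, and on chromosome 14 a share of 0.706 of 17 genes lay on the side. The dimmer genes, whose signal over background is unknown, do not decide between these. DNA was not measured and the GC content of the genes was not tested, so that these stay open.

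By their measured values, members inside the stretches did not carry the whole shift of the Fanconi anaemia and homologous recombination genes. The same holds for the replication-dependent histone genes as measured, but there signal shared between near-identical members keeps the question open. The 5 Fanconi members inside had a mean log2 difference of -0.095 (95% interval from the spread between arrays, -0.26 to 0.07). A mean of 0.56 would be needed to carry the shift of the list. The largest median of a stretch was 0.33, so that this bar could hardly be reached and decides little. The 24 members outside had a mean of 0.14, against 0.097 over all 29, and a median of 0.10, as over all 29. These 24 shifted higher in camera with the preset correlation (adjusted p = 0.0016). Outside the stretches the histone genes (25 of 34 members) shifted higher in camera with the preset correlation (adjusted p = 0.00458), with a mean of 0.14. The 9 inside had a median of 0.21 and a mean of 0.19 (95% interval 0.11 to 0.27), against 0.58 needed to carry the shift of the list. These genes are near-identical in sequence, so that the signal of those outside may include that of those inside. The list calls of the histone and Fanconi genes are lost with an estimated correlation (adjusted p = 0.873 and 0.932), where the members inside were not left out.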
